A study of Homo sapiens with 6 samples.

How the data were processed

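Total RNA from cultured human adipocytes of 2 fat depots was labelled with biotin and hybridised to Affymetrix Human Gene 1.0 ST arrays, per the labels' protocols. Stromal cells were freed from the tissue with collagenase, expanded for 2 passages and kept in adipogenic medium for 7 days, per the labels' protocols, although the extraction note speaks of preadipocytes. The samples were grouped by the depot in the labels, as 3 perivascular arrays (fat around the left coronary artery) and 3 subcutaneous arrays. Numbers 1 to 3 recur in both depots. The series' design text speaks of unrelated donors, and no label ties a number to a donor, so the numbers were not taken to pair the arrays. Nothing in the labels says more on how the replicates of a depot relate, and p-values measure the spread between these 6 arrays.

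The submitters' processing notes name RMA (robust multi-array averaging, which corrects background, normalizes arrays by quantiles and summarises probes), with no version. The deposited values are linear ratios. Each of the 33297 probe sets was divided by its own median over the 6 arrays, as read from the values themselves, since the median of a probe set's 6 ratios equals 1 within 1e-05 in 100% of probe sets. The ratios ran from 0.0186 to 44.1. Because of this centring the brightness of a probe set is lost, so neither its height over background nor its level against another gene can be read, and a ratio shows differences between arrays alone. The direction is settled, a ratio above 1 being a brighter signal in that array. The median ratio per array over all probe sets was 0.998, 1.00 and 0.994 in perivascular replicates 1 to 3 and 1.01, 0.996 and 1.01 in the subcutaneous ones. How the arrays were scanned, and the annotation used at summarisation, are not given in the sources used here. Arrays have no read depth, and their number, 3 per depot, limits the precision.

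Probe sets were named from the platform annotation table. Of the 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none in that table. Symbols were checked through Entrez identifiers against NCBI's RefSeq gene table for GRCh38.p14, where 19429 matched, 31 did not and 0 needed a new symbol. No genome build is named by the files, so no coordinates are given. For the donors' sake, 24 probe sets of chromosome Y genes and of the X inactivation transcripts were left out before any fit. The rest made 18394 genes, of which 768 had several probe sets and took the mean of their log2 ratios.

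Ratios were turned to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 1 coefficient for depot, no covariate). P-values were adjusted by Benjamini-Hochberg over all 18394 genes, with an adjusted p under 0.05 as the threshold. Differences are perivascular minus subcutaneous on the log2 scale, with limma's moderated standard error (SE), n = 3 per depot. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

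The design fixed before the data were examined had assumed expression levels, which the ratios lack, and these steps were therefore changed. A filter on the mean level of a gene was dropped, and so was its stricter form. The mean of a gene's probe sets replaced the brightest probe set. The variance was moderated without a mean-variance trend, and the trend was kept as an alternative. That trend runs over the mean log2 ratio of a gene, which holds no level, so it cannot follow brightness here.

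Before the data were examined, 44 gene lists were also fixed, covering positional transcription factors, adipocyte and vascular biology, inflammation, matrix, signalling, stress and the other cell types such cultures can hold. Each was tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 44 lists, and beside it with camera at a correlation estimated from the arrays and with fry, which asks whether a list's genes move one way (or, in its mixed form, either way) without comparing them with other genes. Member genes were also counted past an adjusted p of 0.05 over all genes and adjusted over the list alone. Adjustment over a list alone does not control errors across the 44 lists, and a gene of several lists can pass in some and miss in others. A gene said to rise or fall over the list alone missed the threshold over all genes unless it is stated to pass there.

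Genes are named by a rule fixed at the same time. It takes up to 15 genes per direction with the largest difference among those past the threshold whose depots do not overlap, or, where a direction has fewer than 10, the 10 with the smallest p and no overlap. It adds up to 4 members with the smallest p per list, any further member past the threshold, and genes of interest chosen from the tissue (ADIPOQ, LEP, PPARG, CEBPA, FABP4, UCP1, IL6, CXCL8, CCL2 and TNFRSF11B). A further gene of interest is not reported here. Excluded were sex-chromosome transcripts of the kinds above, genes often missing from germline genomes, olfactory receptors, small RNAs and placeholder symbols.

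The fit was tested on simulated data for this comparison, with the residual spread of the 18394 genes and 200 genes changed by a known amount. At an adjusted p under 0.05 it recovered 70% of genes changed by 1 on the log2 scale, 93% of those changed by 2 and 97% of those changed by 3. False calls made up 5.41%, 6.06% and 4.90% of all calls. The changed genes were drawn at random from all genes, and each kept the same spread in every array. These shares therefore do not give the power for genes of wider spread, such as ADIPOQ, with a perivascular SD of 2.71. In the data 320 genes differed at least 2-fold, and 17 of them passed the threshold. A simulated shift of 0.5 in 1 list, the adipocyte list, was recovered at a camera adjusted p of 1.19e-04, with 0 unshifted lists called. The genes were simulated as independent, so this does not show how often camera calls lists of correlated genes. In the 6 arrays the estimated correlation of the adipocyte list was 0.449.

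The alternatives were quantile normalization and median centring of the arrays, the mean-variance trend with and without robust moderation, robust moderation alone, array weights, the replicate number as a block, each array left out in turn, other thresholds, the X chromosome left out, the first probe set of each gene, a filter on the spread of a gene, the mean of the adipocyte list as a covariate, and perivascular replicate 3 alone against the subcutaneous arrays. Camera ran alike in the main fit and the settings with a trend or robust moderation, so those settings could change no list call. Counts of list calls over 18 alternatives include those settings.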

Results

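Gene expression was compared between human adipocytes differentiated in culture from fat around the left coronary artery (perivascular, 3 arrays) and from subcutaneous fat (3 arrays). Perivascular fat lies against the vessel wall, and the comparison asks how its adipocytes differ from those of the fat under the skin when both are grown under 1 protocol. Values are deposited RMA signals expressed as the ratio of each array to the median of the 6 arrays, so levels of different genes cannot be ranked. The spread was uneven between arrays. The standard deviation (SD) of the log2 ratio over 18394 genes was 0.36 in perivascular replicate 1, 0.34 in replicate 2 and 0.23 in replicate 3, against 0.24, 0.23 and 0.21 in the subcutaneous arrays. On the first principal component, which held 44.5% of the variance, perivascular replicates 1 and 2 lay at -35.72 and -30.39. Replicate 3 lay at 5.76, and the subcutaneous arrays lay between 19.5 and 20.62.

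The largest rise among the genes past the threshold in the perivascular cultures was that of CEMIP. This gene, which encodes a hyaluronan-degrading protein, was 15.7-fold higher (log2 difference 3.97 ± 0.43 SE, n = 3 per depot, limma adjusted p = 0.0408). ITGA8, the integrin alpha 8 chain found on smooth muscle and mesangial cells, was 12.3-fold higher (3.62 ± 0.39, limma adjusted p = 0.0408). THBS2, a matricellular inhibitor of angiogenesis, was 4.24-fold higher (2.08 ± 0.20), and LAMA1, a laminin chain of basement membranes, was 3.48-fold higher (1.80 ± 0.14). CSGALNACT1, an enzyme of chondroitin sulfate synthesis, rose 4.0-fold, and HEG1, a membrane protein needed for heart and vessel development, rose 3.80-fold. The remaining genes that rose were PRUNE2 (3.56-fold), SH2D4A (2.42-fold), the small GTPase RAB33A (2.13-fold), TMEM87B (1.94-fold) and the laminin-related guidance factor NTN4 (1.93-fold). The 2 probe sets of PRUNE2 differed in the size of the change, at log2 differences of 1.54 and 2.13. Adjusted p-values of these genes lay between 0.0217 and 0.0450.

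The genes that fell in the perivascular cultures included 3 members of the HOXC cluster, homeobox genes whose expression follows position along the body axis. HOXC10 was 5.03-fold lower (log2 difference -2.33 ± 0.14 SE, n = 3 per depot, limma adjusted p = 0.0115), HOXC8 was 3.04-fold lower (-1.61 ± 0.19) and HOXC9 was 2.37-fold lower (-1.24 ± 0.10). TXNIP, a glucose-induced inhibitor of thioredoxin, was 8.86-fold lower (-3.15 ± 0.33, limma adjusted p = 0.0408; 0.664 with the mean-variance trend). MAB21L1, a gene of eye development, was 6.69-fold lower, and PTPN22, a phosphatase best known from lymphocytes, was 4.80-fold lower. PLA2G2A, a secreted phospholipase, fell by 1.65 on the log2 scale, the actin regulator WASF3 by 1.05 and USP18, a brake on interferon signalling, by 0.84. RETREG1, a receptor for turnover of the endoplasmic reticulum, was 5.33-fold lower but missed the threshold (adjusted p = 0.0508).

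**Figure D1:**
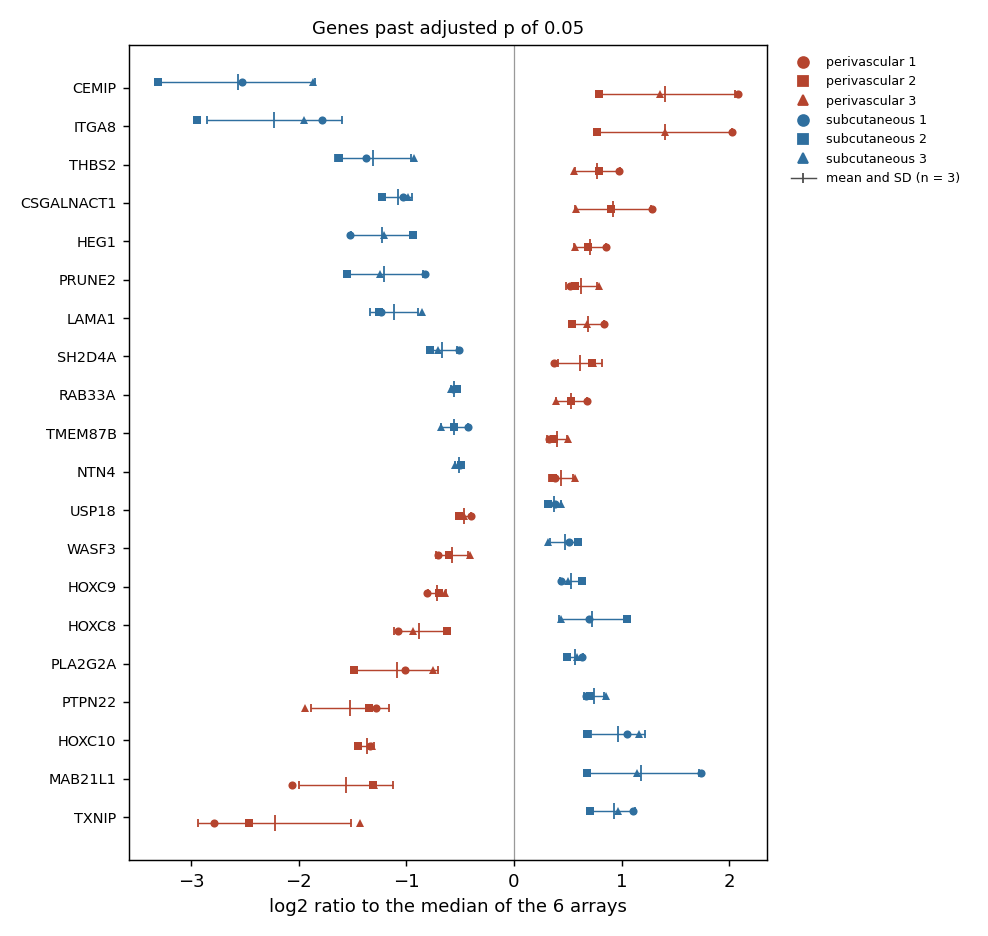
Log2 ratio to the median of the 6 arrays (x axis) for each of the 20 genes past an adjusted p of 0.05 (y axis), with 1 symbol per array and bars for the mean and SD of each depot, n = 3. The depots do not overlap in any gene shown, and centring on the median of the 6 arrays then puts them on opposite sides of 0. For HOXC10 the perivascular values run from -1.44 to -1.32 and the subcutaneous values from 0.68 to 1.16.

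In all, 20 of 18394 genes passed an adjusted p of 0.05, 11 higher and 9 lower in the perivascular cultures, and 17 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 1920 genes, where 919.7 would be expected with no difference. The 3 values of one depot lay beyond the 3 of the other in 2932 genes, or 15.9%, where chance gives 10%. Quantile normalization gave 16 genes, 7 higher and 9 lower, of which 10 were among the 20, whose highest adjusted p became 0.161. The count changed with each array left out. With limma it was 0 without perivascular replicate 1, 0 without replicate 2 and 205 without replicate 3, and 0, 1 and 4 without subcutaneous replicates 1, 2 and 3. In the same order 1411, 1597, 2905, 1650, 1308 and 1487 genes had an unadjusted p under 0.05. Fewer arrays also give less power, so a fall in the count does not show that it rested on the array left out.

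Of 24 listed HOX genes of paralogue groups 6 to 13, 17 were measured. No HOXA gene of the list was among them, nor was HOXC6, so the result covers the HOXB, HOXC and HOXD clusters. Of the 17 measured HOX genes, 14 were lower in the perivascular cultures, with a median log2 difference of -0.20 (camera adjusted p = 1.48e-06; 0.191 with an estimated correlation; fry 0.00193). Of these, 3 fell over all genes tested (HOXC8, HOXC9 and HOXC10) and 5 fell adjusted over the list alone, the further ones being HOXD8 (-0.88 ± 0.19) and, named after its values were seen, HOXB7 (-0.57 ± 0.15). The mean of the list was -0.39, -0.22 and -0.25 in perivascular replicates 1 to 3 and 0.20, 0.21 and 0.23 in the subcutaneous arrays. With perivascular replicate 3 as the sole perivascular array its median was -0.225. Transcription factors of limb, flank and body wall were lower in 19 of 26 genes (median -0.14, camera adjusted p = 0.0351; adjusted p = 0.568 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Examples were SIM1 (-1.52 ± 0.44) and EMX2 (-0.72 ± 0.19). Without perivascular replicate 3 that list had a median of -0.07 (camera adjusted p = 0.0988), and without subcutaneous replicate 3 one of -0.09 (adjusted p = 0.103). HOX genes of groups 1 to 5, which mark more anterior positions, were lower in 7 of 10 (median -0.14, camera adjusted p = 0.0973; past the threshold in 2 of 18 alternatives), with HOXD4 at -0.34 ± 0.09. Factors of cardiac and branchial position were higher in 17 of 29 genes (median 0.07, camera adjusted p = 0.277). Adjusted over that list alone, GATA6, a regulator of heart development, rose (0.86 ± 0.16) and TWIST1, a mesenchymal regulator, fell (-0.71 ± 0.09).

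Genes of the mature adipocyte were lower in 22 of 26 cases in the perivascular cultures, with a median log2 difference of -1.03 (camera adjusted p = 4.36e-05; adjusted p = 0.568 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and the cultures of a depot differed widely. The mean of the list was -1.0, -1.30 and 0.28 in perivascular replicates 1 to 3 and 1.46, -0.26 and 0.27 in subcutaneous replicates 1 to 3. Adiponectin (ADIPOQ) had ratios of 0.137, 0.0532 and 1.99 in the perivascular arrays and 5.60, 0.499 and 1.5 in the subcutaneous ones (log2 difference -2.72 ± 1.40, adjusted p = 0.548). The fatty acid carrier FABP4 (-2.61 ± 1.22), the adipogenic regulator PPARG (-1.02 ± 0.45), the lipid droplet protein PLIN1 (-2.65 ± 0.72), CIDEC (-2.98 ± 0.72) and lipoprotein lipase (LPL, -3.30 ± 0.98) had adjusted p-values from 0.287 to 0.513. CEBPA (-0.20 ± 0.09), leptin (LEP, 0.67 ± 0.93) and the thermogenic uncoupling protein UCP1 (-0.10 ± 0.11) did not pass either. With perivascular replicate 3 as the sole perivascular array, the adipocyte list had a median of -0.03 (camera adjusted p = 0.292).

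Among metabolic lists, fatty acid oxidation genes were lower in 16 of 18 (median -0.50, camera adjusted p = 6.24e-05; adjusted p = 0.568 with an estimated correlation), with DECR1 at -0.74 ± 0.22 and the mitochondrial importer CPT1A at 0.40 ± 0.14. Their mean was -0.37, -0.48 and 0.19 in perivascular replicates 1 to 3 and 0.72, -0.08 and 0.07 in the subcutaneous arrays. The median was -0.05 with the adipocyte mean as a covariate (adjusted p = 0.922) and -0.11 with perivascular replicate 3 as the sole perivascular array (adjusted p = 0.643). Oxidative phosphorylation genes were lower in 24 of 27 (median -0.12, camera adjusted p = 0.00308; adjusted p = 0.669 with an estimated correlation), for example COX6C (-0.66 ± 0.23). Without subcutaneous replicate 1 that median was 0.01 (adjusted p = 0.458), and without perivascular replicate 2 it was -0.06 (adjusted p = 0.110). It was 0.0775 with the adipocyte covariate (adjusted p = 0.279) and -0.00 with perivascular replicate 3 alone (adjusted p = 0.838). Fatty acid and triglyceride synthesis genes were lower in 14 of 20 (median -0.13, camera adjusted p = 0.342), and ACACB was at -2.40 ± 0.68. That list passed in opposite directions, with a median of 0.236 with the adipocyte covariate (adjusted p = 0.0217) and -0.33 without subcutaneous replicate 2 (adjusted p = 0.00642). Brown and beige adipocyte genes were lower in 14 of 23 (median -0.03, camera adjusted p = 0.105), and EBF3 fell adjusted over the list alone (-0.67 ± 0.13). Adipocyte progenitor genes were higher in 13 of 23 (median 0.03, camera adjusted p = 0.256; past the threshold in 2 of 18 alternatives), and the TGF-beta co-receptor ENG rose adjusted over the list alone (1.01 ± 0.20). Cholesterol synthesis genes were higher in 13 of 16 (median 0.26, camera adjusted p = 0.0438; adjusted p = 0.702 with an estimated correlation), with SQLE at 0.85 ± 0.34. That call was lost without perivascular replicate 2 (median 0.08, camera adjusted p = 0.376), subcutaneous replicate 2 (median 0.12, adjusted p = 0.484) or subcutaneous replicate 3 (median 0.24, adjusted p = 0.134). With perivascular replicate 3 alone the median was 0.13.

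Genes of hypoxia and glycolysis gave the smallest p of the 44 lists in camera at the preset correlation, though not with an estimated correlation or in fry. They were higher in 26 of 28 cases (median 0.66, camera adjusted p = 6.84e-08; adjusted p = 0.568 with an estimated correlation), including the glycolytic enzyme PKM (0.63 ± 0.14), the glucose transporter SLC2A3 (0.85 ± 0.22) and HIF1A (0.94 ± 0.27), with 0 members past the threshold over all genes or over the list alone. Their mean was 0.82, 0.31 and 0.02 in perivascular replicates 1 to 3 and 0.03, -0.22 and -0.23 in the subcutaneous arrays. With perivascular replicate 3 alone the median was 0.10 (adjusted p = 0.0281). The unfolded protein response and heat shock list was higher in 22 of 27 (median 0.41, camera adjusted p = 0.00120; adjusted p = 0.568 with an estimated correlation), and its mean was 0.85 in perivascular replicate 2 against 0.07 and -0.03 in replicates 1 and 3. With replicate 3 alone the median was 0.00 (adjusted p = 0.311). HSPB8 (0.89 ± 0.25) and ATF6 (0.41 ± 0.12) were its members with the smallest p-values. Immediate early genes were higher in 16 of 21 (median 0.21, camera adjusted p = 0.00878; adjusted p = 0.568 with an estimated correlation), with IER3 at 0.90 ± 0.30. The adjusted p was 0.119 without perivascular replicate 3 and 0.121 without subcutaneous replicate 1. Ribosomal protein genes were lower in 22 of 31 by a small amount (median -0.12, camera adjusted p = 0.00308; adjusted p = 0.568 with an estimated correlation), with RPL22 at -0.50 ± 0.15. That call ended with the adipocyte covariate (median -0.02, adjusted p = 0.376) and with perivascular replicate 3 alone (median -0.07, adjusted p = 0.359).

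**Figure D2:**
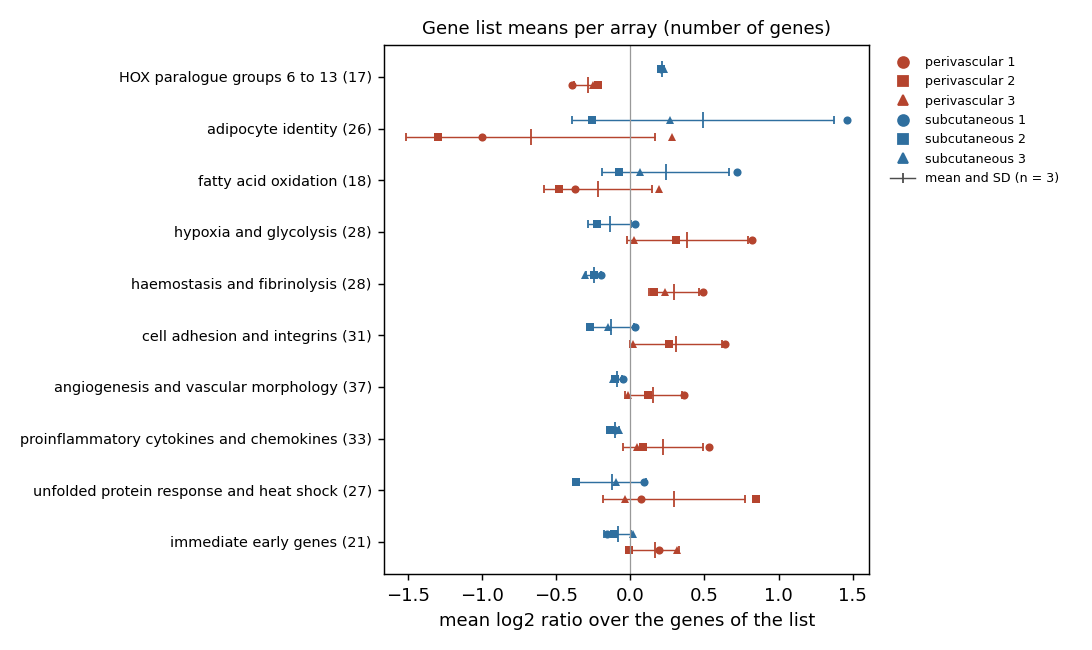
Mean log2 ratio over the genes of a list (x axis) for 10 of the 44 lists (y axis, number of genes in brackets), with 1 symbol per array and bars for the mean and SD of each depot, n = 3. The HOX genes of groups 6 to 13 lie between -0.39 and -0.22 in the perivascular arrays and between 0.20 and 0.23 in the subcutaneous ones, whereas the adipocyte mean of perivascular replicate 3 (0.28) lies inside the subcutaneous range of -0.26 to 1.46.

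Genes of haemostasis and fibrinolysis were higher in 21 of 28 cases (median 0.23, camera adjusted p = 0.00120; adjusted p = 0.434 with an estimated correlation). None rose over all genes tested and 5 rose adjusted over the list alone. These were SERPINE2, an inhibitor of thrombin and plasminogen activators (2.78 ± 0.51), tissue plasminogen activator PLAT (2.05 ± 0.46), the thrombin receptor F2R (1.76 ± 0.43), the urokinase receptor PLAUR (0.49 ± 0.11) and, named after its values were seen, the anticoagulant ANXA5 (0.53 ± 0.14). The list thus held risers that promote clot breakdown and others that restrain it. Its mean was above 0 in the 3 perivascular arrays (0.49, 0.16 and 0.24) and below 0 in the subcutaneous ones (-0.20, -0.24 and -0.30).

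Vascular lists held changes in both directions. Angiogenesis genes were higher in 26 of 37 (median 0.22, camera adjusted p = 0.0152; adjusted p = 0.568 with an estimated correlation; 0.226 without perivascular replicate 1). The median was 0.11 with the adipocyte covariate (adjusted p = 0.279) and 0.02 with perivascular replicate 3 alone (adjusted p = 0.643). Adjusted over the list alone, THBS2, CCN1 (0.93 ± 0.13) and PDGFD (1.45 ± 0.36, named after its values were seen) rose, and the vessel growth factors ANGPT1 (-1.93 ± 0.30) and VEGFC (-0.88 ± 0.21) fell. THBS2 also rose over all genes. Cell adhesion genes and integrins were higher in 23 of 31 (median 0.33, camera adjusted p = 0.00308; adjusted p = 0.568 with an estimated correlation). Of these, 5 rose adjusted over the list alone, namely ALCAM (1.77 ± 0.21), ITGAV (0.83 ± 0.14), CD9 (1.59 ± 0.38), ICAM1 (0.72 ± 0.19) and, named after its values were seen, ITGB5 (0.87 ± 0.25), and PCDH7 fell (-0.52 ± 0.13). ICAM1, also in the adipocyte progenitor and NF-kB lists, did not pass adjusted over either of those, and its limma adjusted p over all genes was 0.310. The adhesion mean was 0.64, 0.26 and 0.02 in perivascular replicates 1 to 3 and 0.04, -0.27 and -0.15 in the subcutaneous arrays. With perivascular replicate 3 alone the median was 0.00 (adjusted p = 0.292). Vasoactive genes were higher in 17 of 29 (median 0.06, camera adjusted p = 0.457; 0.0370 with perivascular replicate 3 alone). Adjusted over the list alone, the prostaglandin receptor PTGER2 (1.55 ± 0.28), the cyclooxygenase PTGS1 (1.97 ± 0.45) and the adenosine receptor ADORA2B (0.91 ± 0.22) rose, and CALCRL, the receptor of adrenomedullin, fell (-1.98 ± 0.33).

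Of the inflammatory lists, 1 passed in camera at the preset correlation. Cytokines and chemokines were higher in 24 of 33 (median 0.16, camera adjusted p = 0.0533; past the threshold in 5 of 18 alternatives, the lowest adjusted p being 0.0140, and a median of -0.04 with an adjusted p of 0.643 with perivascular replicate 3 alone), and 3 rose adjusted over the list alone. These were TNFRSF11B, or osteoprotegerin, at 18.4-fold (4.20 ± 0.81, adjusted p = 0.181 over all genes), IL6 at 3.92-fold (1.97 ± 0.45, adjusted p = 0.273 over all genes) and CXCL16 at 1.89-fold (0.92 ± 0.14). Of these, TNFRSF11B is a secreted receptor that the fixed list holds, and is not itself a cytokine or chemokine. CXCL8 (0.40 ± 0.24) and CCL2 (0.75 ± 0.45) did not pass. NF-kB targets were higher in 15 of 28 (median 0.03, camera adjusted p = 0.306), with TNFAIP6 at 1.01 ± 0.23 and the inhibitor NFKBIA at -0.63 ± 0.16. Interferon response genes were higher in 22 of 32 (median 0.13, camera adjusted p = 0.594), and USP18 and MX2 (-1.74 ± 0.39) fell adjusted over the list alone. Complement genes were higher in 10 of 19 (median 0.00, camera adjusted p = 0.714; 0.0109 with perivascular replicate 3 alone), and C7 rose adjusted over the list alone (3.12 ± 0.64). Antigen presentation genes passed, higher in 10 of 12 (median 0.22, camera adjusted p = 0.0493; adjusted p = 0.568 with an estimated correlation), with TAP2 at 0.34 ± 0.10. That call was lost without perivascular replicate 2 or 3 or subcutaneous replicate 1 or 3 (adjusted p from 0.0633 to 0.199), and with quantile normalization (adjusted p = 0.0526), array weights (0.0897), the first probe set (0.0795) or the adipocyte covariate (0.0700).

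Matrix and mural cell lists did not pass in camera at the preset correlation. Fibrillar collagens and their processing enzymes were higher in 21 of 30 (median 0.23, camera adjusted p = 0.0533; past the threshold in 6 of 18 alternatives; median -0.09 and adjusted p = 0.643 with perivascular replicate 3 alone), with LOXL1 at 0.53 ± 0.17 and COL6A3 at -0.74 ± 0.22. Basement membrane, elastic fibre and proteoglycan genes were higher in 19 of 39 (median -0.01, camera adjusted p = 0.611). There LAMA1 rose, and tenascin C (TNC, -1.94 ± 0.35) and MFAP5 (-1.17 ± 0.26) fell, adjusted over the list alone. Matrix proteases and inhibitors were lower in 16 of 30 (median -0.01, camera adjusted p = 0.290; -0.165 and 0.0289 without perivascular replicate 3), with TIMP3 at -0.91 ± 0.20. Contractile smooth muscle genes were higher in 12 of 22 (median 0.04, camera adjusted p = 0.594), where ITGA8 was the single member to rise over all genes. Pericyte genes were lower in 7 of 14 (median -0.12, camera adjusted p = 0.214), and GJC1 (-0.78 ± 0.11), CSPG4 (-0.60 ± 0.11) and KCNJ8 (-0.52 ± 0.14) fell adjusted over the list alone.

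Lists of other cell types did not pass either. Endothelial genes were higher in 11 of 21 (median 0.01, camera adjusted p = 0.733), macrophage and leukocyte genes in 21 of 26 (median 0.04, camera adjusted p = 0.303) and mesothelial and epicardial genes in 15 of 23 (median 0.07, camera adjusted p = 0.0661; past the threshold in 4 of 18 alternatives, and a median of -0.02 with perivascular replicate 3 alone). In the last list the epicardial factor TCF21 stood at 2.35 ± 0.63, with a ratio of 8.38 in perivascular replicate 1, and WT1 at 0.40 ± 0.13. Cardiomyocyte genes were higher in 9 of 18 (median -0.01, camera adjusted p = 0.594), and MYL3 fell adjusted over the list alone (-0.61 ± 0.13). Schwann cell and neuron genes were higher in 11 of 18 with a median of 0.03 and a mean of -0.15 (camera adjusted p = 0.823), and neurofilament NEFL was at -1.42 ± 0.32.

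Signalling and growth lists did not pass in the same test. TGF-beta and BMP genes were higher in 22 of 32 (median 0.25, camera adjusted p = 0.105; past the threshold in 4 of 18 alternatives; median -0.04 and adjusted p = 0.945 with perivascular replicate 3 alone), with ID2 at 1.19 ± 0.30 and TGFB2 at -1.18 ± 0.35. WNT genes were higher in 19 of 39 with a median of -0.00 and a mean of 0.09 (camera adjusted p = 0.652), and the WNT antagonist DKK1 rose adjusted over the list alone (1.92 ± 0.32). Notch and hedgehog genes were higher in 15 of 24 with a median of 0.04 and a mean of -0.00 (camera adjusted p = 0.594), and HES1 was at -0.36 ± 0.14. IGF axis genes were higher in 9 of 16 (median 0.17, camera adjusted p = 0.775), and PAPPA2, a protease of IGF-binding proteins, fell adjusted over the list alone (-1.99 ± 0.30). Retinoid genes were higher in 13 of 25 with a median of 0.00 and a mean of -0.20 (camera adjusted p = 0.591), with RXRA at -0.38 ± 0.12. Glucocorticoid and steroid genes were lower in 18 of 26 (median -0.10, camera adjusted p = 0.132), with SGK1 at 1.14 ± 0.26. Axon guidance and neurotrophic genes were higher in 16 of 31 (median 0.01, camera adjusted p = 0.457), and NTN4 rose over all genes. Cyclin-dependent kinase inhibitors and p53 targets were higher in 12 of 18 (median 0.11, camera adjusted p = 0.173), with PLK2 at 2.12 ± 0.56. Cell cycle genes were higher in 19 of 38 with a median of 0.01 and a mean of -0.02 (camera adjusted p = 0.591), with CENPE at -0.35 ± 0.11. They passed downward without perivascular replicate 3 (median -0.09, adjusted p = 0.0131) and upward with it alone (0.0839, adjusted p = 0.00126). Chondro-osteogenic genes were higher in 13 of 21 (median 0.10, camera adjusted p = 0.107), with BMP2 at 0.45 ± 0.14.

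With an inter-gene correlation estimated from the 6 arrays, 0 of the 14 called lists stayed past the threshold, and fry in its directional form called 1 list, the HOX genes of groups 6 to 13. In its mixed form, where members can move either way, fry called 20 of 44 lists, 5 of them among the 14. The other 15 included axon guidance (adjusted p = 8.65e-06), interferon response (3.35e-04), complement, the IGF axis and cardiomyocyte genes (each 0.00481) and cytokines (0.0371).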

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

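Of the tests in this part, those on adipocyte and HOXC genes in perivascular replicate 3, on the HOX genes with and without the adipocyte covariate and on the count of genes over splits were chosen after the results were seen. Those on endothelial cells, leukocytes and cardiomyocytes, on cytokines and the count of lists over splits were chosen before. The first of these was at first worded as cells of any other type and was narrowed after its value was seen, with its lists and bound unchanged. Probe sets with no gene symbol in the annotation lie outside the comparison of named genes, and 2 of 12083 passed an adjusted p of 0.05 between the depots, with 1002 at an unadjusted p under 0.05 where 604.15 would be expected.

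The lower adipocyte genes were uneven between cultures of the perivascular depot. Endothelial cells, leukocytes and cardiomyocytes as the cause of the lower adipocyte genes are argued against by their markers. The lists tested were the endothelial, macrophage and leukocyte, and cardiomyocyte lists. Over these lists the highest upper 95% bootstrap limit of the median log2 difference was 0.11, below the bound of 0.25 set in advance. The interval of the macrophage and leukocyte list, 0.016 to 0.11, lay above 0, so a small share of leukocytes is not excluded. These medians average the perivascular arrays, though adipocyte genes were low in replicates 1 and 2. In those 2 the endothelial mean was 0.03 and 0.15, against -0.02 to 0.02 in the subcutaneous arrays. The macrophage and leukocyte mean was 0.01 and 0.09, against -0.05 to 0.04. The cardiomyocyte mean was 0.03 in both, against 0.04 to 0.09. A small share of endothelial cells in replicate 2 is thus not excluded either. Signal over background is unknown. Of the genes of these lists, 4 of 21, 0 of 26 and 4 of 18 are in another list too. Mesothelial and epicardial cells, whose list was not in that test and was higher in 15 of 23 genes (camera adjusted p = 0.0661; past 0.05 in 4 of 18 alternatives), stay open, as do fibroblasts and undifferentiated stromal cells. Weak differentiation of perivascular replicates 1 and 2 alone stays open too, since the value behind it, an adipocyte mean of 0.28 in replicate 3 inside the subcutaneous range of -0.26 to 1.46, is what prompted it and cannot test it. That value was at first read as bearing it out. A difference between depots in how readily cells differentiate, or between donors, stays open and was not tested.

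The lower HOX genes may follow the extent of differentiation, and 2 tests bear on it, the second added once the first had not decided. In perivascular replicate 3, whose adipocyte genes lay in the subcutaneous range, the mean of 7 HOXC genes was -0.368, and it lay -0.63 from the lowest subcutaneous array (0.26). Less the width of the subcutaneous range, which the test asked it to exceed, that distance was -0.42, with a bootstrap interval over genes of -1.26 to 0.39. That test was first read without the interval, as arguing against differentiation, and the interval took that reading away. With the adipocyte mean as a covariate the median over the 17 HOX genes of groups 6 to 13 was -0.174, against -0.204 without it, with a camera adjusted p of 1.13e-05 (1.48e-06 to 0.191 over all alternatives, the highest with an estimated correlation) but a fry adjusted p of 0.0527, just short of the bound set for it. The same covariate took fatty acid oxidation genes from a median of -0.50 to -0.05. In the subcutaneous arrays the mean of the HOX list stayed between 0.20 and 0.23 while the adipocyte mean ran from -0.26 to 1.46. In perivascular replicate 3, whose adipocyte mean of 0.28 lay in that range, the HOX mean was -0.25. In the subcutaneous arrays the HOX mean thus did not move with the adipocyte mean. Perivascular replicate 3 is 1 array, however, and these tests were chosen after the results were seen. The covariate correlated with depot at -0.637, so the fit separates differentiation from depot only in part. These values do not decide whether differentiation, as read from the adipocyte list, is the whole cause for these 17 genes. The bound asked for fry as well as camera and was not met, so a part played by differentiation stays open. A positional difference between the depots, which the design names, stays open.

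The cytokine list, which leaned upward, could also follow differentiation. Its mean in perivascular replicate 3 was 0.0443, which is 0.12 above the highest subcutaneous array (-0.07). Less the width of the subcutaneous range that distance was 0.06, with a bootstrap interval of -0.29 to 0.25. The distance rests largely on the member TNFRSF11B. Its ratio was 2.99 in perivascular replicate 3 and 0.447, 0.1045 and 0.196 in subcutaneous replicates 1 to 3. With perivascular replicate 3 alone the median difference of the list was -0.04, against 0.16 with all 6 arrays. The mean and the median thus point opposite ways, and the part of differentiation stays open. The interval was brought in after the value was seen.

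There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 20 genes and the highest of the other splits 0, so that 1 of 10 splits gave as many. For lists the real split gave 14 and the highest other also 14, so that 2 of 10 gave as many; the other was perivascular replicates 1 and 2 with subcutaneous replicate 2, the arrays with the lowest adipocyte means.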

How the results depend on the processing

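The covariate, the first probe set, robust moderation alone, the filter on spread and the use of perivascular replicate 3 alone were chosen after seeing the data. Of 193 named genes, at most 7 changed sign in a setting, with perivascular replicate 3 alone. All 20 called genes kept their sign in the 16 settings that refit them, but not their calls. Since the depots do not overlap in any of the 20, leaving out or weighting arrays could not turn a sign. Nor could the moderation settings or the replicate block, which leave the difference as it was. The count of genes past the threshold stayed within 1.5 times of 20 with quantile normalization (except genes higher, 7 against 11), median centring, the trend, array weights, the first probe set, robust moderation alone, the X chromosome left out or a 2-fold minimum. Of the 20, 20 stayed past with array weights and with the first probe set, 17 with median centring, 16 with the trend, 16 with robust moderation alone and 10 with quantile normalization. With the trend, which has no level to follow here, TXNIP reached a limma adjusted p of 0.664. The count moved to 98 (47 higher, 51 lower) with the trend and robust moderation, 12 of them among the 20, 55 (25 and 30) with the filter on spread, which is no independent filter since the SD it uses includes the depot difference, 42 (18 and 24) at an adjusted p under 0.10, 237 (118 and 119) at an unadjusted p under 0.05 with a 2-fold minimum, and 2 (1 and 1) with perivascular replicate 3 alone, which is assumed to vary like the subcutaneous arrays. With the covariate limma called 0 (0 and 0) of 1153 genes at an unadjusted p under 0.05; the smallest adjusted p among the 20 was 0.0754. HOXC10 stood at -2.33 before and -2.20 after. Leaving out 1 array at a time gave 0 to 205 genes (0 to 92 higher, 0 to 113 lower). With the replicate number as a block the count was 4 (2 and 2), 2 of them among the 20; deviations of same-numbered arrays correlated at -0.011, -0.037 and -0.005, none of the arrays correlated best with its own number, and the pairing was not used. The number of lists was 9 with the covariate, 0 with an estimated correlation and 1 with directional fry, and 11 to 17 with 1 array left out. Of the 30 lists not called, 11 passed in at least 1 alternative. The adipocyte list has no value with the covariate, which is made from it. Among lists past the threshold in either fit, the direction of the camera test turned for fatty acid and triglyceride synthesis (median 0.236) and oxidative phosphorylation (0.0775) with the covariate and for the cell cycle (0.0839) with perivascular replicate 3 alone. List medians of any size changed sign in 14 of 44 lists with perivascular replicate 3 alone, 7 of 43 with the covariate and at most 9 of 44 in another setting. Apart from what is stated of sample number and construction, the cause was not tested. The filters on dim genes were not run, since the ratios hold no level, and neither was the list median with and without that filter; signal over background is unknown.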

Other observations

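Some named genes not described above differed without overlap between the depots yet missed the threshold over all genes. The complement factor CFB was 4.19-fold higher in the perivascular cultures (adjusted p = 0.340), the peptidase DPP4 2.68-fold higher (adjusted p = 0.318) and the WNT antagonist DKK2 2.56-fold lower (adjusted p = 0.310), each in 3 of 3 arrays. The 3 probe sets of CFB gave log2 differences from 2.03 to 2.14. STC1, a secreted glycoprotein, had ratios of 16.7, 4.03 and 1.11 in perivascular replicates 1 to 3 and 0.893, 0.496 and 0.544 in the subcutaneous arrays (adjusted p = 0.360). In ADH1B, whose depots overlap, the values were uneven within the perivascular depot. This alcohol dehydrogenase, an enzyme of retinol oxidation, had ratios of 0.0533, 0.214 and 1.03 in perivascular replicates 1 to 3 and between 0.97 and 1.34 in the subcutaneous ones (adjusted p = 0.459).

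Within the perivascular depot the log2 ratios of replicates 1 and 2 correlated across genes at 0.37, those of replicates 1 and 3 at 0.02 and those of replicates 2 and 3 at -0.15. Genes are not independent replicates, and centring on the median of the 6 arrays lowers such correlations. The ratio of LEP was 7.44 in perivascular replicate 1, where that of ADIPOQ was 0.137.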
